A study of Mus musculus with 16 samples.

How the data were processed

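Genomic DNA from the tails of 8 mice of 1 C57BL/6JNrs family (sire, dam and 6 F1 progeny) was compared with DNA of 1 reference male of the same colony by array comparative genomic hybridisation, in which sample and reference DNA carry different dyes and compete for the probes of an oligonucleotide array. Per the labels, each mouse was hybridised on 2 arrays with the dyes swapped, so that there were 16 arrays, 4 on each of 4 slides. The 2 arrays of a mouse measure the same DNA and counted as 1 replicate. Slide 1 held the sire and the dam, slide 2 F1 1 and F1 2, slide 3 F1 3 and F1 4, and slide 4 F1 5 and F1 6. The probes were not a sample of the genome: per the series' design text they were placed densely around probes that had stood out in an earlier screen of this family. Counts of regions therefore describe preselected places, and the same family was used to pick them.

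The deposited scanner files were made with Agilent Feature Extraction 12.1.0.3, per the file headers, and give probe coordinates on mouse build mm9. Per the file headers, the processed red and green signals are intensity values that had been background-subtracted, detrended and dye-normalised within each array. The deposited log ratio of each spot is on a log10 scale, red over green, per the file headers. It equalled the log10 ratio of the processed signals with a median difference of 0 on every array and a largest difference of 0.0939. The value table of the series holds log2 values deposited by the authors, and how they were made is not given in the sources used here. Set against log2 of red over green of the same array, its columns correlated at 0.969 to 1.00 in size with slopes of 0.94 to 1.00 in size, and the sign followed the dye orientation on all 16 arrays. The table thus ran as reference over mouse, opposite to the direction used here, on a log2 scale. Its column medians lay between -0.0008 and 0.0131, so the columns were centred near 0, by a method that stays unknown.

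Every value here is log2 of mouse over reference. Log2 of red over green was taken from the processed signals, turned in sign where the mouse was in Cy3, and centred on the median of the 134862 genomic spots of its array, with no loess or quantile step. Control spots (6563 per array) and spots with an outlier flag (115 to 203 per array) were left out, and spots of 1 probe were averaged, which gave 128025 probes. The value of a mouse is the mean of its 2 orientations, and the number after ± is the distance of either orientation from that mean (n = 2 arrays of 1 mouse, a technical error only). Of the genomic spots, 99.82% to 99.86% per array were well above background in both channels and 0 were saturated. The derivative log ratio spread given in the file headers was 0.102 to 0.122. Over the autosomal probes, arrays of different mice in 1 orientation correlated at 0.39 to 0.82 with the mouse in Cy5 and 0.57 to 0.83 with the mouse in Cy3. The 2 orientations of a mouse, both as mouse over reference, correlated at only -0.44 (sire) to 0.23 (F1 3), so that most variation between probes did not repeat when the dyes were swapped. Calls therefore required both orientations.

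Autosomal probes (127974) were split into runs wherever neighbouring starts lay over 50 kb apart. The 1635 runs of at least 5 probes held 124444 probes, with a median of 75 probes and 10917 bp per run and a median spacing of 91 bp. The 3530 probes in shorter runs entered no call. Each mouse was segmented by recursive circular binary segmentation with a robust standard deviation from successive differences and a segment z of at least 6. A segment was called where it held at least 5 probes, its mean lay at least 0.25 from 0 and each orientation lay at least 0.15 from 0 on the same side. Overlapping calls of the 8 mice were merged into regions. The value of a region in a mouse is the mean over all its probes. Progeny-only segments are F1 calls where each parent, over the same probes, had under 50% of the F1 mean on the same side. For transmission, a region called in 1 parent, with the other parent under 50% of its mean, was carried by an F1 mouse with over 50% of the mean of the parent. Carriage was set against 50% by an exact two-sided binomial test, counting 1 region per 5 Mb, the one with the largest value. The sex chromosomes (48 X probes and 3 Y probes) served as a check of scale and dye direction. Tiles of 10 consecutive probes (at least 5, none across a gap over 50 kb; 12495 tiles, median span 1180 bp) were tested with limma. Differences between mice used the moderated F test over 16 arrays with a dye term, Benjamini-Hochberg adjustment at 0.05 and a range over mice of at least 0.25. This test measures the 8 DNA samples against the dye-swap error and not against variation between animals of a group. F1 was compared with the parents on per-mouse means (n = 6 and 2). Sire and dam share slide 1, so a slide effect there is part of the generation difference; slide was fitted as a random block as an alternative.

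Regions were named by a rule fixed before the data were examined: up to 25 called regions by the largest absolute value in any mouse, up to 10 progeny-only regions in the same order, and up to 10 tiles of each limma test by the smallest adjusted p, at most 1 per 1 Mb. Gene names were not used here, because the scanner files give none and the gene table at hand is on another build. The planned test of gene groups in copy number regions was therefore not run, nor was the planned trend on probe GC, since no probe sequence was used here. The normexp alternative used median spot signals in place of means. The alternatives were normexp with an offset of 50, loess, the series' value table, filters on dim and flagged spots, single orientations, other thresholds, gaps, lengths, tile sizes and baselines, and leaving out each F1 mouse (for the generation test, each parent too). Added after seeing the data were a minimum of 20 probes, removal of the trend with probe length, and leaving out both F1 mice of slide 3.

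The segmentation was tested on simulated data: noise of the measured size was placed at the 127974 autosomal probe positions with 200 planted segments. All planted segments were found (100% at log2 sizes of -1, 0.35 and 0.58), with 0 calls elsewhere. A noise component shared by all mice was then added with no planted segment, drawn independently for each probe. It gave 0 calls and 0 regions called in all 8 mice. Noise of that kind averages out over a segment, so this does not test a shared error that spans neighbouring probes. The test between mice, on 12495 simulated tiles with 200 changed ones, called 100% at sizes of 0.35, 0.58 and 1, with 1 false call. The test of F1 against parents called 98.6% at 0.35 and 100% at 0.58 and 1, with 11 false calls. There the change was planted in all F1 mice alike, on noise with no correlation within slides. Detection of a change in a single F1 mouse was therefore not tested. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and R 4.3.3 with limma 3.58.1.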

Results

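Array comparative genomic hybridisation was used to look for DNA copy number differences in a single mouse family: a sire, a dam and 6 of their F1 progeny, each set against 1 reference male. The question here was whether progeny carried copy number changes that neither parent carried. The series title names a family of males exposed to gamma rays at 0.05 mGy per day for 400 days, whereas the design text lists the sire of this family as not irradiated. The labels thus conflict, the family has no control family beside it here, and no value below is ascribed to dose. With 1 sire, 1 dam and 1 litter, comparisons between single mice rest on dye-swapped arrays of the same DNA and not on replicate animals. All values are log2 of mouse over reference, the reverse of the direction in the study's own value table.

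The sex chromosomes gave the scale of a doubling in copy number. Over 48 X probes the median was 0.95 in the dam and 0.97 in F1 4, F1 5 and F1 6, against 0.00 in the sire, 0.01 in F1 1 and -0.01 in F1 2 and F1 3. The reference was male, so that a mouse with 2 X chromosomes stood close to a doubling. The Y probe starting at 731532 was not well above background on any array of the dam, F1 4, F1 5 and F1 6, whereas it measured -0.03 in the sire, 0.06 in F1 1, -0.15 in F1 2 and 0.22 in F1 3. In the dam, F1 4, F1 5 and F1 6 the Y probe starting at 784163 measured -4.13 to -3.66. The one starting at 1673660 measured only -0.88 to -0.65 in the same mice. At the probe starting at 784163, F1 4 (-4.13) and F1 5 (-3.66) had a spot well above background on only 1 of 2 arrays. Both ends of that range are therefore uncertain. In the dam, F1 4, F1 5 and F1 6 the X values were above 0 in both dye orientations, for example 0.91 and 1.00 in the dam, and thereby matched the labelled dyes. In the other 4 mice they lay between -0.05 and 0.07 in either orientation.

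The longest copy number region was a gain on chromosome 4, from 101109394 to 101270967 in mm9, which spanned 161574 bp and 1108 probes and was called in all 8 mice. It took 2 separate levels. The sire measured 0.53 ± 0.04, F1 2 0.54 ± 0.03, F1 3 0.52 ± 0.03 and F1 4 0.54 ± 0.03, which are ratios of 1.43 to 1.45 to the reference. The dam measured 0.92 ± 0.05, F1 1 0.93 ± 0.04, F1 5 0.93 ± 0.04 and F1 6 0.93 ± 0.04, ratios of 1.89 to 1.90. The levels were 0.38 apart at their closest, several times the difference between orientations. The 20 probes before the gain averaged between -0.02 and 0.03 in the 8 mice, and the 20 probes after it between -0.03 and 0.03. Tile by tile, the same step stood among the smallest adjusted p-values between mice (1.931e-12, limma moderated F test with Benjamini-Hochberg adjustment), at the tile from 101177008 to 101178061.

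**Figure D1:**
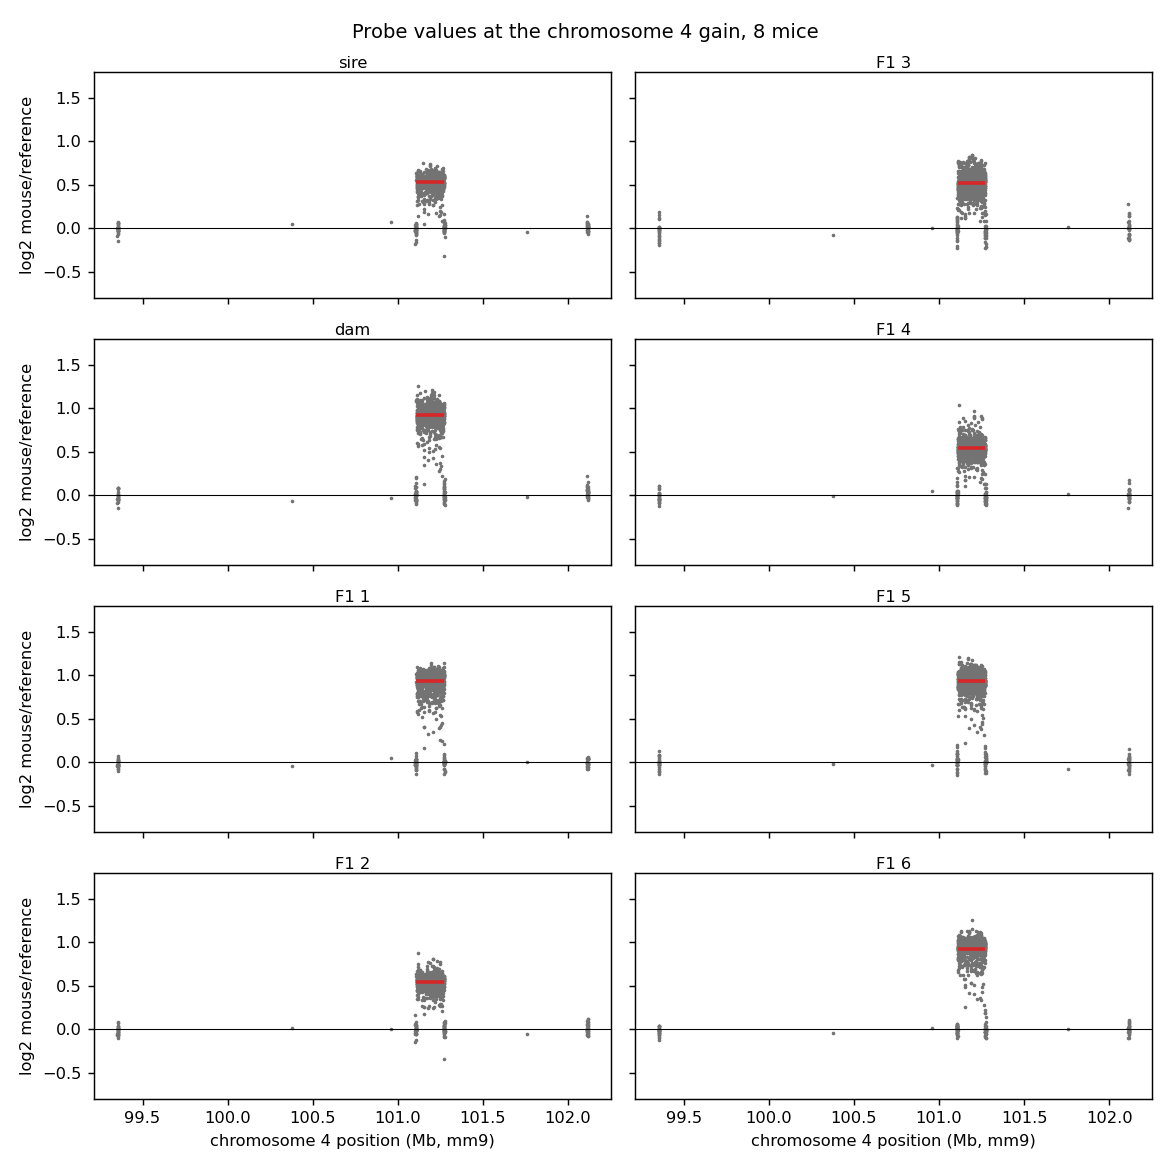
Log2 of mouse over reference (vertical axis) against position on chromosome 4 in Mb (horizontal axis) in a panel for each of the 8 mice; grey points are probes (mean of 2 dye-swapped arrays) and the red line is the mean over the 1108 probes of the gain. The red line lies at 0.52 to 0.54 in the sire, F1 2, F1 3 and F1 4 and at 0.92 to 0.93 in the dam, F1 1, F1 5 and F1 6, and probes on either side lie near 0.

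Chromosome 14 held all other regions called in the 8 mice together, and there every mouse was below the reference. From 53708609 to 53764803, the 45 probes measured between -0.84 (F1 2) and -0.79 (F1 3). A further 4 regions followed on the same stretch. From 53972530 to 53992405 values ran from -0.48 (F1 1) to -0.29 (dam), from 54108715 to 54160090 from -0.50 (F1 4) to -0.44 (F1 6), and from 54238081 to 54332250, over 56 probes, from -0.41 (F1 1) to -0.31 (F1 2). From 54371340 to 54386879 they ran from -0.45 (sire) to -0.37 (F1 4 and F1 5). All arrays share 1 reference mouse, so a value shared by 8 mice does not show on which side of the ratio the difference lies. Noise in a shared reference, simulated as independent between probes, gave 0 such regions. That simulation could not give a shift over neighbouring probes, so it does not bear on this stretch. Whether this stretch rearranges in somatic cells, as antigen receptor loci do, was not tested, so these losses, and the F1 1 and F1 2 losses on the same stretch, are not shown to be in the germ line.

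A short loss lay on chromosome 1, where the region from 153211661 to 153212551 averaged -1.50 in the dam, -0.34 to -0.28 in the 6 F1 mice and -0.01 in the sire. It rested on 2 overlapping probes of the 7. At the first, from 153212126 to 153212185, neither array of the dam was well above background, so that its ratio there is only a bound. All 6 F1 mice lay between -1.01 and -0.88 at this probe, close to 50% of the reference signal, and the sire was at 0.00. At the second, from 153212134 to 153212193, the F1 mice measured -1.04 to -0.90 and the sire -0.02. The nearest probes on either side, starting at 153212083 and 153212395, measured -0.15 and 0.00 in the dam, so the strongly reduced stretch was shorter than the distance between them. With all probes near background left out the dam averaged -0.02 over the region, and with normexp -0.60, so the size of the loss in the dam is not measured, while at these 2 probes every F1 array was well above background.

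**Figure D2:**
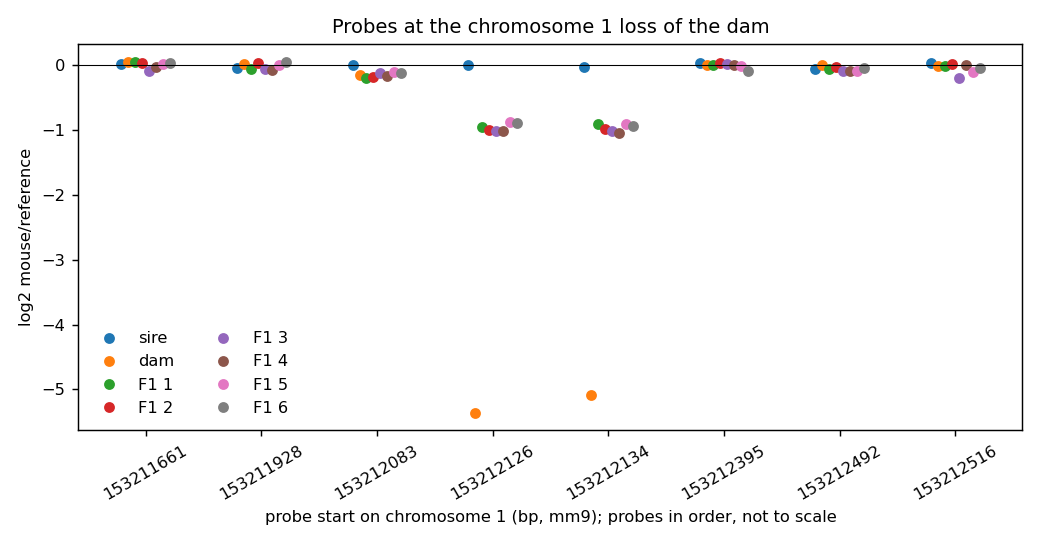
Log2 of mouse over reference (vertical axis) at 8 neighbouring probes on chromosome 1, in order of position (horizontal axis, start in mm9), with a point for each of the 8 mice. At the probes starting at 153212126 and 153212134 the dam lies below -5 (at or near background), the 6 F1 mice between -1.04 and -0.88 and the sire at 0.00 and -0.02.

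On chromosome 3, from 25421508 to 25444229, the dam (-1.41), F1 4 (-1.37), F1 5 (-1.38) and F1 6 (-1.41) were low, while the sire (0.00), F1 1 (0.01), F1 2 (-0.08) and F1 3 (0.10) stayed near the reference. These are the mice that were low and near 0 at the Y probes. In all, 10 autosomal regions followed the X profile with a correlation of at least 0.9 in size over the 8 mice, among them a gain on chromosome 8 from 102237046 to 102239604 (0.30 in the dam, 0.32 in F1 4, 0.33 in F1 5, 0.31 in F1 6) and a loss on chromosome 5 from 123597144 to 123599126 (-0.45, -0.46, -0.45 and -0.46 in the same mice).

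Altogether 991 segments were called, which merged into 345 regions: 261 with gains only, 78 with losses only and 6 with both. Most were short. The median length was 693 bp, 317 regions held under 10 probes and 5 held at least 20. The dam had 164 gained segments and the sire 15; F1 3 had 219, F1 4 209, F1 1 72, F1 6 33, F1 5 23 and F1 2 13. Lost segments numbered 24 in the sire, 26 in the dam and 21 to 28 in the F1 mice other than F1 3, which had 72. Several segments of a mouse can lie in 1 region, so counts by region were lower. Regions with gains numbered 139 in the dam, 3 in the sire, 209 in F1 3, 197 in F1 4, 33 in F1 1, 8 in F1 6, 7 in F1 5 and 5 in F1 2. Regions with losses numbered 67 in F1 3 and 9 to 16 in the other mice. The spread between neighbouring probes was also largest in F1 3, at 0.082, against 0.042 to 0.058 in the other 7 mice. The region count was 638 with a minimum of 3 probes, 154 with 10, 183 with a threshold of 0.4, 529 from the arrays with the mouse in Cy3 alone and, in an alternative added after seeing the data, 176 without F1 3 and F1 4.

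**Figure D3:**
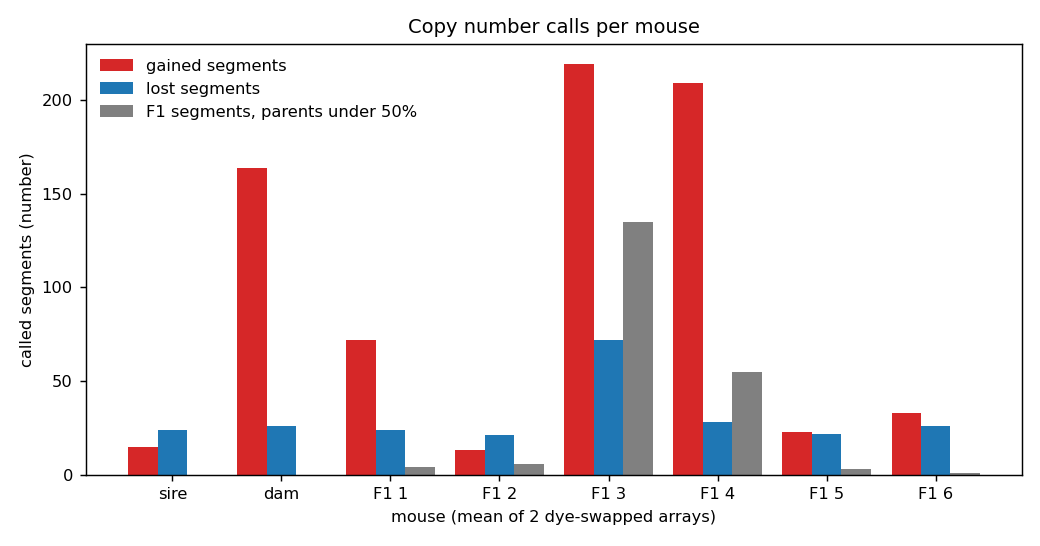
Number of called segments (vertical axis) in each mouse (horizontal axis): gained segments in red, lost segments in blue, and, in grey, F1 segments over which each parent had under 50% of the F1 value. Gains range from 13 in F1 2 to 219 in F1 3, and the grey counts from 1 in F1 6 to 135 in F1 3. Several segments of a mouse can lie in 1 region, and by region gains range from 3 in the sire to 209 in F1 3.

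The short regions largely shared 1 profile over the mice. Among the 339 regions not called in every mouse, a single profile held 81.8% of the variance between mice, and 212 regions on 19 chromosomes correlated with it at 0.9 or more in size, 190 of them gains and 22 losses. In the gains the median value was 0.54 in F1 3, 0.34 in F1 4, 0.30 in the dam, 0.15 in F1 1, 0.13 in F1 6, 0.04 in F1 5, 0.03 in the sire and -0.04 in F1 2, with a median difference of either orientation from the mean of 0.037 to 0.045. Of the 25 regions with the largest values, 22 had this graded profile, at 0.88 to 1.09 in the highest mouse and 228 to 1250 bp in length. The region on chromosome 15 from 11267875 to 11268179 measured 1.09 in F1 3, 0.64 in F1 4, 0.57 in the dam, 0.27 in F1 1, 0.18 in F1 6 and 0.06 in the sire. On chromosome 18, from 59288466 to 59289066, the values in the same order were 1.04, 0.66, 0.57, 0.26, 0.24 and 0.08. On chromosome 2, from 19839213 to 19840462, they were 0.92, 0.56, 0.49, 0.29, 0.21 and 0.05.

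**Figure D4:**
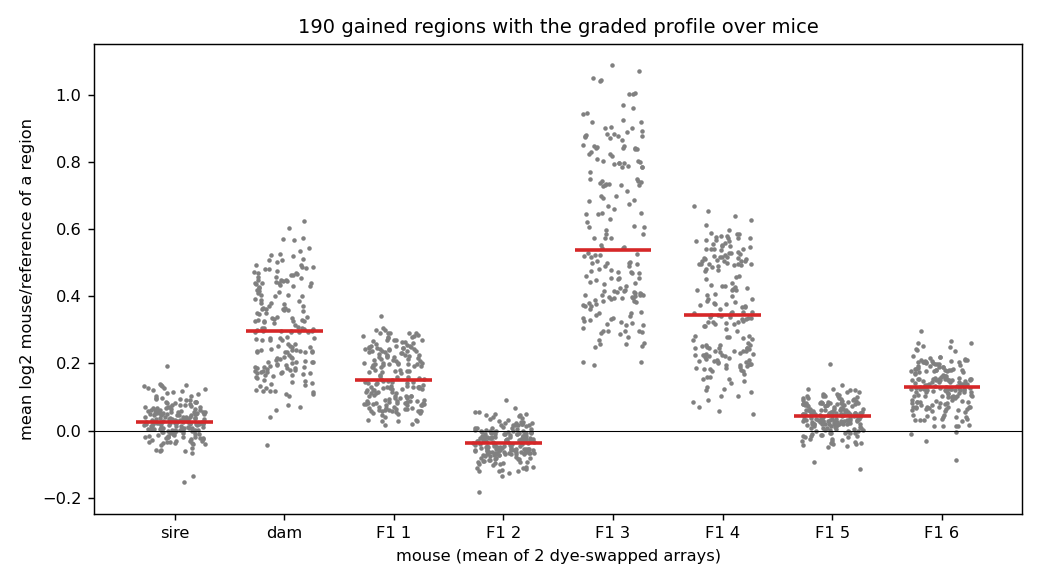
Mean log2 of mouse over reference (vertical axis) of each of the 190 gained regions with the graded profile, by mouse (horizontal axis); a grey point is a region and the red line the median of a mouse. Medians fall from 0.54 in F1 3 over 0.34 in F1 4 and 0.30 in the dam to -0.04 in F1 2.

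Segments of F1 mice over which each parent had under 50% of the F1 value were counted as progeny-only, whether or not a parent was called there too. There were 204 such segments in 189 regions, 126 with gains only, 61 with losses only and the rest with both. F1 3 held 135 of the segments and F1 4 55, and the other 4 F1 mice held 14 together (F1 2 6, F1 1 4, F1 5 3 and F1 6 1). The median segment had 5 probes, the longest 15, and 7 had at least 10. All 10 regions with the largest values were gains in F1 3. The largest, on chromosome 14 from 13264938 to 13265388, measured 1.07 in F1 3 with 0.51 in the dam and 0.02 in the sire. On chromosome 5, from 50895458 to 50895928, F1 3 measured 0.97 and the dam 0.45. On chromosome 7, from 68790312 to 68790956, F1 3 measured 0.92 and the dam 0.43. In all 10 the dam was raised too, at 0.36 to 0.51, and fell short of 50% of the F1 value. The dam was itself called at all 10, so they are differences in degree and not a presence set against an absence. Without F1 3 there were 61 such regions, and without both mice of slide 3, an alternative chosen after seeing the data, 11.

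Among the 14 segments of the other 4 F1 mice, named after their values were seen, the largest was a loss in F1 1 on chromosome 14 from 53987464 to 53992292 (-0.59; -0.51 and -0.66 in the 2 orientations), inside a region called in all 8 mice, with -0.26 in the sire and -0.14 in the dam over the same probes; the sire was itself called over part of it (-0.59, from 53987464 to 53991911). F1 2 had a loss of -0.42 from 54062540 to 54078675 on the same chromosome, with -0.07 in the sire and 0.01 in the dam. F1 1 and F1 2 also had losses on chromosome 2. Near 70084179 F1 1 measured -0.40 (-0.20 and -0.59 in the 2 orientations), and near 70086401 F1 2 measured -0.27. F1 3 (-0.25) overlapped the first and F1 1 (-0.25) the second. The dam was called as a gain (0.38) from 70082725 to 70083275. Single probes nearby swung in both directions: F1 2 measured 1.79, -1.18 and 0.85 at those starting at 70085479, 70085571 and 70085615. On chromosome 11 the losses were in F1 6 from 76358590 (-0.31, sire 0.20, dam 0.17) and in F1 1 from 76359288 (-0.34, sire 0.10, dam 0.08). The sire was itself called as a gain (0.29) on chromosome 11 from 76359019 to 76359567, overlapping both losses. Some gains of these 14 were shared with siblings: F1 2 (0.32) and F1 4 (0.47) on chromosome 7 from 78693709 to 78693927, F1 2 (0.29) and F1 4 (0.45) on chromosome 7 from 137374581, where F1 3 (0.28) overlapped, and F1 2 (0.31) with an overlapping segment of F1 4 (0.37) on chromosome 12 from 17321643. The sire lay below the reference over these F1 2 segments, at -0.18, -0.18 and -0.16, and the other F1 mice lay between sire and F1 4 in all of these regions, so they were graded over the family too. Each mouse gave 1 DNA sample, so whether any of the 14 is present in the germ line was not tested.

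Transmission was counted for regions called in 1 parent alone. There were 108 regions at least 5 Mb apart, 104 from the dam and 4 from the sire. The F1 mice carried them in 289 of 648 cases, or 44.6% (95% interval 40.7% to 48.5%, exact Clopper-Pearson, counting error only), which differed from 50% (exact two-sided binomial test, p = 0.00667). The individual mice were far from that mean. F1 4 carried 102 of the 108, F1 3 100, F1 1 63, F1 6 20, F1 5 3 and F1 2 1, so the regions did not behave as independent events and the pooled p-value is too small. Of the 108 regions, 98 had the graded profile, and these were carried in 275 of 588 cases (46.8%). The 3 that followed the X profile were carried in 9 of 18 cases. The 7 of other profile, among them the chromosome 1 loss, were carried in 5 of 42 (11.9%). The pooled share thus rests mostly on graded regions. The pooled share depended on the mice in it: 41.9% (p = 0.000176) without F1 1, 53.3% (p = 0.132) without F1 2, 35.0% (p = 2.95e-12) without F1 3, 34.6% (p = 8.27e-13) without F1 4, 53.0% (p = 0.182) without F1 5 and 49.8% (p = 0.966) without F1 6, each by the exact test. It was 20.1% (p = 2.01e-37, exact) without F1 3 and F1 4, an alternative added after seeing the data, and 19.9% (p = 1.13e-19, exact) over 36 regions when each mouse was set against the median of the 8 mice. The chromosome 1 loss entered with 0 carriers because the F1 values lay under 50% of the value of the dam on the log2 scale, although all 6 F1 mice were low.

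Regions called in the sire alone were few, and 2 of them were present in 3 F1 mice each. On chromosome 4, from 117397266 to 117397510, the sire measured -0.43, with -0.45 in F1 2, -0.43 in F1 3 and -0.40 in F1 4, and between -0.06 and 0.00 in F1 1, F1 5 and F1 6. On chromosome 13, from 95704529 to 95708219, the sire measured 0.36, with 0.34 in F1 3, 0.36 in F1 4 and 0.34 in F1 6, against 0.00 to 0.04 in the others. These 2 regions were named after their values were seen.

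Between the 8 mice, 279 of 12495 tiles differed (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05 and a range of at least 0.25), or 2.2%. The mouse farthest from the median was F1 3 in 181 of the 279, the sire in 28, F1 1 in 17 and F1 2 in 16. The smallest adjusted p, 1.315e-20, belonged to the chromosome 3 tile from 25421508 to 25443259, with -1.54 in the dam and 0.00 in the sire. Next came graded tiles on chromosome 2 from 19839249 (adjusted p = 7.102e-14; F1 3 0.95, dam 0.51, sire 0.04), chromosome 19 from 50707512 (adjusted p = 1.348e-13; F1 3 0.83, dam 0.43, sire 0.03) and chromosome 6 from 118964138 (adjusted p = 2.576e-13; F1 3 0.77, dam 0.43, sire 0.05). A further 5 of the 10 tiles with the smallest adjusted p had this profile: those on chromosome 11 from 9145018, chromosome 3 from 133585944 and from 34505869, chromosome 6 from 147188236 and chromosome 15 from 11267074. The median residual spread of a tile over arrays was 0.0274. The count was 175 without F1 3 and F1 4, an alternative added after seeing the data, and 1201 with no minimum range.

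F1 and parents did not separate at any tile in their group means, a comparison that is not a test for changes in single F1 mice. With 6 F1 mice and 2 parents, 0 of 12495 tiles had an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment; smallest adjusted p 0.998), and 503 tiles, 4.03%, had an unadjusted p under 0.05. The tile with the smallest p, on chromosome 6 from 18454656 to 18455337, had an F1 mean of 0.07 against a parent mean of -0.04, a difference of 0.11 ± 0.02 (SE). The next, on chromosome 4 from 124218668, had means of 0.05 and -0.05, and on chromosome 3 from 123796297 they were 0.05 and -0.04. On chromosome 4 from 94723087 the F1 mean of 0.03 was below the parent mean of 0.11. Without the sire, 3 tiles passed, named after their values were seen: those on chromosome 1 from 153211209 and from 153212134, which hold the probes where the dam was at or near background, so that their size in the dam is not measured, and on chromosome 7 from 47256907 (dam -0.22, sire 0.03, F1 mice 0.06 to 0.11; adjusted p = 0.002424, limma). That fit compares the F1 mice with the dam alone, whose spread was taken to be that of the F1 mice. With slide as a random block, 0 tiles passed.

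The dam and the sire, both on slide 1, differed by at least 0.25 in each orientation at 137 tiles, higher in the dam at 134 and lower at 3. There is no test, as each is 1 mouse. The dam was lower at the chromosome 3 tile from 25421508 (-1.54 ± 0.02). It was also lower at the chromosome 1 tile from 153211209, where the size is not measured because probes of the dam were at or near background. The dam was higher at the chromosome 4 gain, for example by 0.49 ± 0.01 at the tile from 101202896, and at the graded tiles on chromosome 2 from 19839249 (0.47 ± 0.02) and chromosome 11 from 9145018 (0.42 ± 0.02). Over all tiles the median absolute difference was 0.022 and the median distance of an orientation from the mean 0.015.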

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

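A mouse far from the other 5 F1 mice was looked for in 63 measures and found in 2, both times F1 3. For independent measures chance alone singles out about 1 in 20, and 2 would be no more than chance gives. Many of the 63 came from regions and tiles of the same graded profile. They are not independent, so whether 2 exceed chance is not known. F1 3 had 72 lost segments against 28 in the next mouse, and its spread between neighbouring probes was 0.082 against 0.058 in the next mouse. Among the tests below, all but the one on the share of full-length probes were chosen after the result was seen.

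F1 3 also led the graded profile of short regions. The dam and the sire shared slide 1 and differed by 0.27 in the median of its 190 gained regions. This argues against a slide effect as the whole cause. The regions were picked for the profile, so the gap only restates that the profile parts 2 mice of 1 slide. A slide effect as part of the cause stays open, since the highest mice, F1 3 (0.54) and F1 4 (0.34), shared slide 3. Independent inheritance of many separate copies is argued against, because 5 of the 6 F1 mice carried a share of the counted regions away from 50% (exact binomial test, Bonferroni adjusted p of 1.39e-10 or less in each of the 5, and 0.609 in F1 1). These p-values are too small where regions on 1 chromosome are linked. The counted regions were picked for a call in 1 parent and not for the profile. As 98 of the 108 had the profile, the shares of the mice largely restate it. Carriage was also a cut-off at 50% of the value of the parent, set on a graded value. A trend with probe length as the whole cause is argued against by its removal: F1 3 averaged 0.60 over the probes of these regions before and 0.60 after, although its median over the shortest probes was -0.10 against 0.02 over the longest. Base composition may still contribute and cannot be told apart here: full-length probes were more frequent in the gains than in the same runs outside regions by 6.5 percentage points (66.3% against 59.8%), and no probe sequence was used. The state or preparation of the DNA samples and a biological difference between the mice stay open, as untested.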

How the results depend on the processing

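Alternatives to the counts kept their size within 1.5 times, and those to the share transmitted their side of the threshold, except as follows; 20 probes, probe length and the removal of slide 3 were added after seeing the data. In the order regions, progeny-only regions and share transmitted, the mouse in Cy3 alone gave 529, 118 and 48.6%, 10 probes 154, 59 and 45.5%, a threshold of 0.4 gave 183, 59 and 46.5%, and 20 probes 65, 25 and 41.7%, with none of these shares past the binomial threshold (p = 0.157 to 0.532 by the exact test). A minimum of 3 probes gave 638 and 441. The minimum length enters the segmentation itself. Normexp gave a share of 47.0% (p = 0.182, exact) and loess 47.7% (p = 0.298, exact). Against the mean of sire and dam, 356 regions were called in the F1 mice. Without both F1 mice of slide 3 there were 176 regions, 11 progeny-only and 175 tiles between mice, with a share of 20.1%; against the median of the 8 mice the share was 19.9% over 36 regions. Both shares stayed below 50% but fell far from 44.6%. Those tiles numbered 761 at 5 probes, 118 at 20 probes, 1201 with no minimum range and 171 with a range of 0.4. Leaving out each F1 mouse gave 237 to 345 regions, 61 to 189 progeny-only and a share of 34.6% to 53.3%, which passed above 50% without F1 2 (53.3%) and without F1 5 (53.0%) and was 49.8% without F1 6. Leaving out each mouse gave 0 to 3 tiles between F1 and parents, and the other settings gave 0 (212 to 833 at an unadjusted p under 0.05; limma). Dam minus sire gave 133 tiles with normexp and 134 with loess. Of 43 single values, among them several regions counted under 2 naming rules, 28 moved by more than the spread between orientations with normexp, 11 with loess, 9 without the probe length trend, 2 with the value table and 1 without dim probes, and 0 changed sign. A single orientation cannot exceed that spread, so it tests nothing here. Beyond the removal of mice and construction, the cause was not tested. The trend on probe GC and the gene group tests were not run. No paired analysis was possible because all F1 mice had the same sire and dam, which leaves no pairs between the groups. Signal over background limits the chromosome 1 loss of the dam, which went from -1.50 to -0.02 without dim probes and to -0.60 with normexp.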

Other observations

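All tests in this part were chosen after the results were seen. A loss on chromosome 3 from 137106573 to 137107193 was present in the sire (-0.42), with F1 mice between -0.11 and 0.12. A second profile was shared by 30 regions on 13 chromosomes, 29 of them with progeny-only calls. In these regions the median was highest in F1 4 (0.29), at 0.18 in F1 3 and 0.16 in F1 2, and lowest in the sire (-0.09). The regions were picked for this profile, so its order over the mice is fixed by the choice. Of the 3530 probes too isolated to enter a call, 1 reached 0.7 in both orientations of a mouse: the chromosome 13 probe from 47492428 to 47492487, with 0.83 in F1 4 and -0.50 in the sire.

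The chromosome 4 gain at 2 levels has a candidate explanation in inherited copies. A slide effect is argued against, since F1 1 and F1 2 shared slide 2 and differed by 0.39. If the sire carried the gain on 1 chromosome of the pair and the dam on both, with none in the reference, each F1 mouse would take the level of a parent, and the largest distance of an F1 mouse from the nearer parent was 0.015, with 3 mice at each level. The F1 mice at the level of the sire were also those with the loss of the sire 16.1 Mb away on chromosome 4, which held in 6 of 6 mice. With 6 mice a match this good arises in a share of 0.1 of assignments by chance, so linkage and chance cannot be told apart.

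For the chromosome 3 region, an autosomal deletion inherited from the dam alone is argued against only if sire and reference hold the sequence on both chromosomes. An F1 mouse would then keep an allele of the sire and stay above -1, whereas the least negative of the low F1 mice was at -1.37. A sire at the reference level does not show this. If sire and reference both lacked the sequence on a single chromosome of the pair, F1 mice could take the level of the dam. An autosomal deletion is therefore not excluded. Copies on the Y chromosome that bind the same probes cannot be told apart from other causes. Region and Y probes were both low or both near 0 in 8 of 8 mice. The region was named for the size of its value (rank 2) and not for this match. A match this good arises in a share of 0.0143 of assignments by chance, but the test was chosen after the match was seen. That share also makes no allowance for the number of regions, of which 10 followed the X profile. The X probes part the same mice in the opposite direction, at 0.95 in the dam and 0.97 in F1 4, F1 5 and F1 6. More copies on the X chromosome would raise the region in these mice, so its low values argue against such copies. Which sequence the probes share was not tested, as no genome sequence was used here.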
